A study of Mus musculus with 13 samples.

How the data were processed

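H3K4me3, a histone mark of active promoters, was measured by chromatin immunoprecipitation and sequencing in the hippocampus of C57BL/6 mice, in 13 libraries. Methionine synthase (Mtr) had been removed from the central nervous system by Cre recombination of floxed exons 4 and 5, with Cre driven by the Thy-1.2 promoter, per the labels' protocols. SRT2104, an agonist of the deacetylase SIRT1, was given by gavage at 50 mg/kg from day 15 to day 36, in 9 administrations at 3 per week. The vehicle was DMSO in PEG. The groups were wild type with vehicle (n = 4), wild type with SRT2104 (n = 3), knockout labelled as not treated (n = 2) and knockout with SRT2104 (n = 4). The untreated knockouts are not labelled as given vehicle, so gavage cannot be separated from genotype or compound in the comparisons they enter. Chromatin was fixed, sonicated and precipitated with an antibody against H3K4me3, per the labels' protocols. The labels do not say whether each library is a separate mouse, or which shared a litter or a day, so p-values measure the spread between these libraries.

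The deposited table gives the signal of each library in each H3K4me3 region, a read count divided by 1 factor per library. Reads were placed on the mouse genome build mm9, and Bowtie2, SAMtools, bedtools, MACS2 and DESeq2 are named without versions or roles, per the submitters' processing notes. Input controls and the rule for calling regions are not given in the sources used here. In the deposited table each region is listed with the promoter windows of 2500 bp that it overlaps, so a region near several promoters fills several lines. The 17212 lines were reduced to 14006 distinct regions, of median length 1484 bp, that carry 14523 gene names. The authors' deposited table also gives a log2 fold change and a p-value per region for knockout against wild type. That log2 fold lay within 0.02 of the ratio of the untreated knockout mean to the wild-type vehicle mean in 99.5% of regions. The adjusted p-values in the authors' deposited table fit an adjustment over 25295 regions, more than are listed, so regions away from promoters were not analysed here. In the authors' deposited table an adjusted p under 0.05 was given for 4 listed regions: Thy1 (log2 fold 0.85), Eif2s3y (-22.50), Nlrp5-ps (-1.30) and Ube2ql1 (0.29).

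All values (100%) were whole multiples of 1 step per library, within a tolerance of 0.001 reads, in all 13 libraries, so whole reads could be recovered. The smallest value above 0 was 1 read in 7 libraries and 2 to 4 reads in the other 6. Reads within regions ranged from 3963196 in wild-type SRT2104 replicate 1 to 9009109 in knockout SRT2104 replicate 2, with medians of 277 and 632 reads per region. Reads are not independent molecules, since PCR copies cannot be told apart. Column names in the deposited table carry a sex letter. Xist and the Y-linked genes Eif2s3y, Ddx3y and Uty fitted that letter in all 13 libraries, of which 5 were female and 8 male. Both untreated knockouts were female and all 4 wild-type vehicle mice male, so sex is confounded with genotype there, and its effect is estimated from the SRT2104 groups.

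The design written before the data were examined assumed raw counts and named edgeR. Because the deposited values are scaled, the main test was instead limma's moderated test with a mean trend and robust variances on log2(value + 1), over all 13 libraries with 1 coefficient per group. Fold changes on this scale understate the change of low regions. Regions needed a normalized count of 10 in at least 2 libraries, which removed 0 of the 14006 regions. Significance was a two-sided Benjamini-Hochberg adjusted p under 0.05 over all regions. With no effect, an unadjusted p under 0.05 would be reached by that share of regions on average, so such counts are not calls. On the recovered reads, edgeR's quasi-likelihood test, DESeq2 and limma voom with sample quality weights were alternatives. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

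The 25 gene lists, the comparisons and the rule for naming genes were also fixed before the data were examined. The lists cover the methionine and folate cycle, cobalamin transport and processing, H3K4 methylation and demethylation, sirtuins and NAD, SIRT1 substrates, the unfolded protein and heat shock response, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, the excitatory synapse, immediate early genes, GABAergic interneurons and hippocampal excitatory neurons. The others are neural development, myelin and oligodendrocytes, astrocytes, microglia, vascular cells, choroid plexus and ependyma, neighbouring brain regions, Hox clusters, imprinted genes, sex chromosome markers, DNA and other methyltransferases, and ribosomal proteins. Each was tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 25 lists of a comparison. Each of 14523 genes was represented by its region with the highest mean. With the estimated correlation 0 lists passed in any comparison. The fry test, which asks whether the members of a list move on balance 1 way, was a further alternative.

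Named regions follow that rule. Where at least 5 regions passed in a direction, up to 12 were to be named, and otherwise the 5 smallest p-values in that direction, said not to have passed where they did not. The rule adds up to 4 members with the smallest p-values from each list that passed, and Mtr and Sirt1. Some genes that the rule names are not reported here. Regions named outside it are said to have been chosen after their values were seen.

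The steps were tested on simulated data over 14006 regions, with 50 regions changed at each fold. A 1.5-fold change was recovered in 94% of regions for untreated knockout against wild-type vehicle, 84% for treated against untreated knockout, 88% for wild-type SRT2104 against vehicle, 82% for treated knockout against wild-type SRT2104 and 90% for treated knockout against vehicle. For a 1.2-fold change the shares were 38%, 46%, 60%, 52% and 64% in the same order. In that order 8, 6, 14, 14 and 5 unchanged regions were called. Noise was drawn independently for each region and library, and no simulated library lay apart from its group. These shares therefore check the steps, and do not measure what could be recovered from the real libraries. Alternatives changed the scaling, the tool, the filter, the pseudocount, the regions used, the groups in the fit and the region per gene. Others added sex or the replicate number to the model, or left out each library in turn. Members of lists above and below 0 were also counted on log2 values scaled by TMM.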

Results

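H3K4me3 was profiled in 13 libraries of mouse hippocampus to ask how loss of methionine synthase in the central nervous system, and the SIRT1 agonist SRT2104, alter the mark at promoters. Methionine synthase makes methionine from homocysteine with a cobalamin cofactor, and so feeds the methyl donor of histone methyltransferases. Values are normalised read counts per region, as mean ± SD over the libraries of a group. Log2 differences are on the log2(value + 1) scale, with the SE where it is given. Coordinates are mm9 and each region overlaps a promoter window. Wild-type vehicle groups had n = 4, wild-type SRT2104 n = 3, untreated knockout n = 2 and knockout SRT2104 n = 4, and reads in regions per library ranged from 3963196 to 9009109.

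The targeted gene was examined first. The Mtr promoter region (chromosome 13, 12349305 to 12350575) had 489 ± 2.67 in wild-type vehicle, 493 ± 22.9 in wild-type SRT2104, 469 ± 58.9 in untreated knockouts and 468 ± 23.4 in treated knockouts. The deleted exons lie downstream of this promoter, so its signal does not check the knockout. Sirt1, which encodes the target of SRT2104 (chromosome 10, 62800635 to 62802383), had 894 ± 19.5, 802 ± 104, 906 ± 97.1 and 893 ± 71.2 in the same order. Neither region passed in any of the 5 comparisons or the interaction.

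Sex was visible in known places. With sex in the model, 13 regions differed, of which 9 lay on chromosome X and were higher in females. They included Xist (female minus male log2 7.75) and the genes Kdm5c (0.67), Ddx3x (0.70) and Eif2s3x (0.74), which escape X inactivation. Eif2s3x had 647 ± 40.8 in 5 females and 390.0 ± 20.6 in 8 males. Of the others, 3 were the Y-linked Eif2s3y, Ddx3y and Uty, and 1 was the autosomal Vps41 (-0.33).

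Libraries resembled each other closely. Spearman correlations across regions, which are not independent replicates, were 0.984 to 0.994 within groups and 0.978 to 0.995 between groups. No replicates agreed within sampling noise, with a chi-square per degree of freedom of 1.31 to 3.31. The first principal component, computed without chromosomes X and Y, held 27.2% of the variance. On it the untreated knockouts scored 12.2 and 21.6 and wild-type vehicle replicate 3 scored 17.2, while the other 10 libraries lay between -9.27 and -0.720. Of its 10 largest loadings 8 were on chromosome 17, among them Dynlt1b, H2-Q5 and H2-T10. Without that chromosome the untreated knockouts scored 15.7 and 16.2, vehicle replicate 3 16.5 and the other 10 libraries -7.27 to -1.09.

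**Figure D1:**
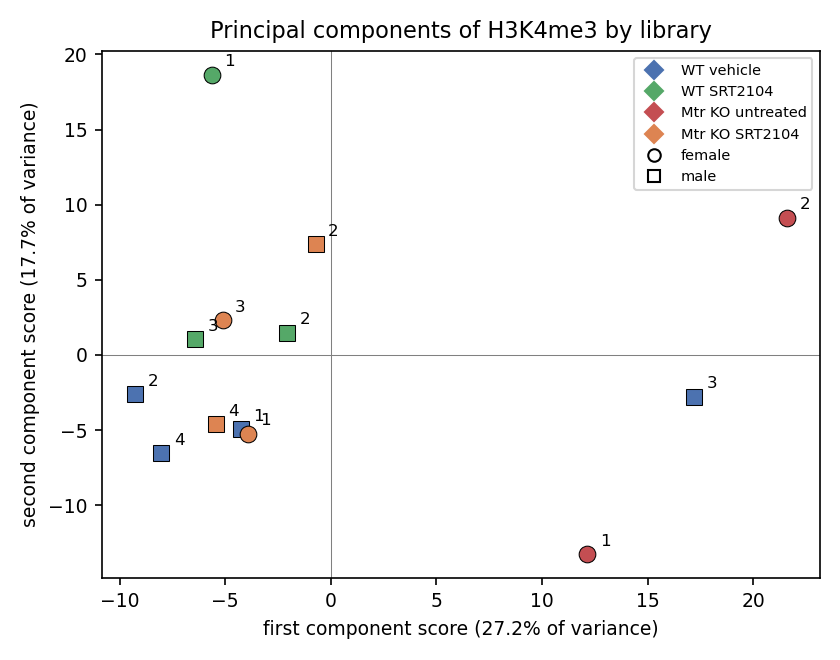
Scores of the 13 libraries on the first and second principal components of the log2 values of autosomal regions, with colour for group, circles for females and squares for males. The untreated knockouts and wild-type vehicle replicate 3 lie at 12.2 or more on the first component, and the other 10 libraries below 0.

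Untreated knockouts were compared with wild-type vehicle mice to ask what loss of methionine synthase does to the mark. Thy1, which encodes a surface glycoprotein of neurons (chromosome 9, 43851054 to 43853496), rose from 649 ± 79.99 to 1171 ± 126, a log2 difference of 0.85 (SE 0.11, limma adjusted p = 0.0446). The Cre transgene of the knockouts uses a Thy-1.2 promoter, per the labels' protocols. No other region passed. That includes the Y-linked Eif2s3y, Ddx3y and Uty, at 0 in both untreated knockouts and 294 to 393 in the vehicle libraries. It also includes Xist, at 670 and 731 against 0.868 to 6.48. The main fit has no sex term, and its spread also comes from SRT2104 groups of mixed sex. A region that did not pass can therefore still differ. Among the higher regions with the next smallest p-values were the chaperone gene Calr (679.7 ± 22.4 and 831 ± 71.5, log2 0.29) and the septin gene Sept9 (0.37). Among lower regions they were Wnt10a, a Wnt ligand (109 ± 8.06 and 62.6 ± 20.4, log2 -0.83), the lysosomal protease gene Ctsz (-0.44), Nlrp5-ps (-1.22), Adssl1 (-0.36) and Mafa (-0.44), and none of these passed.

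As groups, myelin, Hox, choroid plexus and neighbouring-region genes had less signal in untreated knockouts, relative to all other genes. Myelin and oligodendrocyte genes were lower in 28 of 32 members, with a median log2 of -0.24 (camera adjusted p = 9.51e-12, adjusted p = 0.361 with an estimated correlation). Examples were the transcription factor gene Zfp488 (139 ± 22.5 and 94.7 ± 25.1), Ninj2 (log2 -0.86) and the transferrin gene Trf (-0.59), while the myelin basic protein gene Mbp had 0.16. Hox genes, which pattern the hindbrain and trunk, were lower in 13 of 13 (median -0.41, adjusted p = 1.16e-09, adjusted p = 0.129 with an estimated correlation), among them Hoxa5 (19.8 ± 2.43 and 8.30 ± 1.62) and Hoxd3 (log2 -1.06). Choroid plexus and ependyma genes were lower in 11 of 14 (median -0.24, adjusted p = 3.65e-05, adjusted p = 0.402 with an estimated correlation), such as Foxj1, a regulator of motile cilia (log2 -0.38), and Enpp2 (-0.25). Markers of neighbouring brain regions were lower in 27 of 35 (median -0.10, adjusted p = 1.57e-05, adjusted p = 0.361 with an estimated correlation), such as Pax3 (-0.71) and Sim1 (-0.46), while the cortical gene Fezf2 had 0.46. In wild-type vehicle replicate 3 the list medians, relative to the vehicle mean, were -0.36 for myelin, -0.27 for Hox, -0.25 for choroid plexus and -0.11 for neighbouring-region genes. On the same scale the myelin medians of the untreated knockouts were -0.222 ± 0.274 (mean ± SD), and replicate 2 carried most of that fall. With 1 library left out and relative to the median of all genes, the myelin median went from -0.277 to -0.424 without vehicle replicate 3 and -0.114 without untreated knockout replicate 2. Hox genes went from -0.445 to -0.779 without untreated knockout replicate 2, and did not pass at -0.345 without untreated knockout replicate 1. Markers of neighbouring regions went from -0.130 to -0.199 without vehicle replicate 3 and -0.207 without untreated knockout replicate 2, and did not pass at -0.0850 without untreated knockout replicate 1.

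Astrocyte genes had more signal in 29 of 33 members (median log2 0.15, adjusted p = 1.86e-05, adjusted p = 0.256 with an estimated correlation). They included S100b (94.7 ± 15.1 and 131 ± 11.9, log2 0.48) and the gap junction gene Gjb6 (0.42). Excitatory synapse genes were higher in 54 of 59 (median 0.11, adjusted p = 8.90e-08, adjusted p = 0.402 with an estimated correlation), among them Cacng8 (520.0 ± 33.8 and 643 ± 31.8) and Grik5 (log2 0.22). With sex as a covariate the excitatory synapse list had an adjusted p of 0.0551. Oxidative phosphorylation genes (68 of 77 higher, median 0.06, adjusted p = 0.00734) and ribosomal protein genes (64 of 74 higher, median 0.05, adjusted p = 0.0493) were close to the median of all genes of 0.03. Both had an adjusted p of 0.827 with an estimated correlation and neither passed after loess scaling, with Ndufc2 at 0.17 and Rpl12 at 0.19. Adjusted over the list alone, 7 excitatory synapse and 2 astrocyte genes were higher and 2 Hox genes lower, against 0 of these over all regions tested. In wild-type vehicle replicate 3 the medians were 0.03 for astrocyte, 0.10 for excitatory synapse, 0.07 for oxidative phosphorylation and 0.06 for ribosomal genes. Of all genes 32.8% were below 0 here and 49.9% with TMM scaling, where 47 of 59 excitatory synapse, 27 of 33 astrocyte, 54 of 77 oxidative phosphorylation and 50 of 74 ribosomal genes were above 0. Relative to the median of all genes, and with 1 library left out, the oxidative phosphorylation median was 0.0275 with all libraries and did not pass at 0.0216 without vehicle replicate 4 and 0.0165 without untreated knockout replicate 1. Ribosomal genes went from 0.0185 to 0.0379 without untreated knockout replicate 2, and did not pass at 0.00798 without vehicle replicate 1, 0.0161 without vehicle replicate 4 and -0.00159 without untreated knockout replicate 1.

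**Figure D2:**
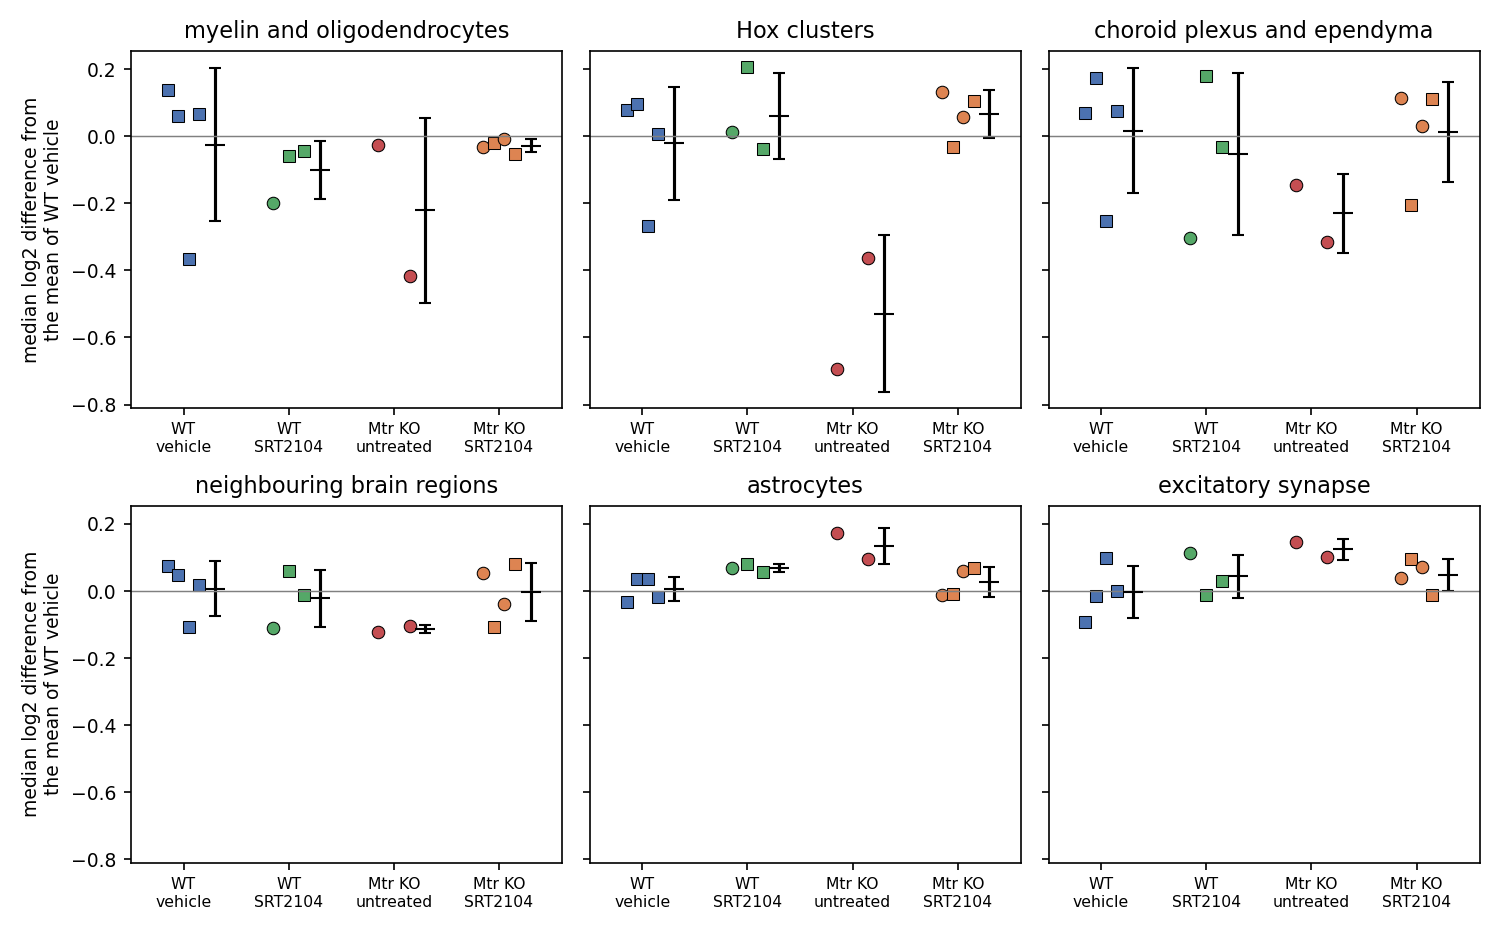
Median log2 difference from the wild-type vehicle mean over the measured genes of each list, 1 point per library by group, with circles for females, squares for males and a bar for the group mean ± SD. Myelin genes lie at -0.36 in wild-type vehicle replicate 3, and at -0.03 and -0.42 in the untreated knockouts.

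The number of regions called rested on single libraries. Without wild-type vehicle replicate 3, 564 regions passed (380 higher and 184 lower) against 1 with it, 0 passed without replicate 2 or 4, 5 without either untreated knockout, and 2 without vehicle replicate 1. With sex as a covariate 0 regions passed by limma (831 at an unadjusted p under 0.05, and 1280 without the covariate). Thy1 then had 0.69 (adjusted p = 0.578, in a range of 1.00e-06 to 0.703 over all settings). Without the covariate edgeR called 0 regions (1357 at an unadjusted p under 0.05) and DESeq2 called 25. Those 25 included the Y-linked Ddx3y and Uty, where females are compared with males, and H2-Ab1 and H2-Q7 on chromosome 17. The lists called numbered 6 without untreated knockout replicate 1, where Hox, neighbouring-region, oxidative phosphorylation and ribosomal genes did not pass, and 13 without replicate 2.

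**Figure D3:**
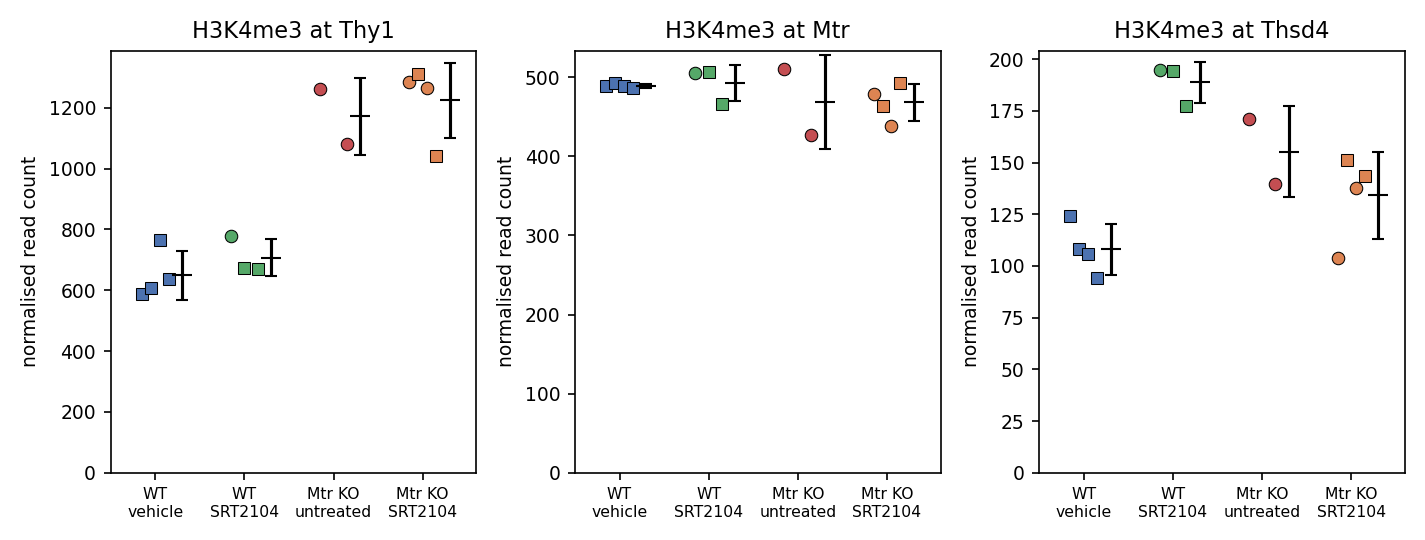
Normalised read count at the promoter regions of Thy1, Mtr and Thsd4, 1 point per library by group, with circles for females, squares for males and a bar for the group mean ± SD. At Thy1 the 6 knockout libraries lie between 1042 and 1310.2 and the 7 wild-type libraries between 588 and 778.

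Treated knockouts were compared with untreated knockouts to ask what SRT2104 does in the knockouts. No single region passed. Those with the smallest p-values and more signal after treatment were Insm2, a neuroendocrine transcription factor gene (286 ± 0.557 untreated and 382 ± 27.6 treated, log2 0.41), Mcidas, a regulator of multiciliated cells (116 ± 7.27 and 204 ± 30.6, log2 0.80), Wnt10a (0.88), a region of the neural progenitor gene Pax6 (1.00) and Ctsz (0.47). Those with less signal included Tmem100 (247 ± 12 and 159 ± 13.9, log2 -0.63), the pericyte receptor gene Pdgfrb (297 ± 6.16 and 207 ± 9.78, -0.52), the phosphatase gene Dusp1 (-0.34) and Tnfaip8l3 (-0.41). Thy1 had 1171 ± 126 and 1225 ± 123 (log2 0.06, adjusted p = 0.799).

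This comparison and the one of untreated knockouts with vehicle hold the same 2 untreated knockouts with opposite sign, so opposite directions of a list arise in them even with no effect of treatment. Hox genes were higher in 13 of 13 members (median log2 0.44, camera adjusted p = 1.25e-10, adjusted p = 0.0893 with an estimated correlation), with Hoxd3 at 11.4 ± 5.41 untreated and 28.01 ± 1.74 treated. Myelin genes were higher in 24 of 32 (median 0.24, adjusted p = 5.91e-10, adjusted p = 0.491 with an estimated correlation), with Myrf, a regulator of myelin genes, at 0.41. Choroid plexus and ependyma genes were higher in 10 of 14 (median 0.27, adjusted p = 3.95e-06, adjusted p = 0.491 with an estimated correlation), such as Lmx1a (0.60). Markers of neighbouring brain regions were higher in 24 of 35 (median 0.14, adjusted p = 1.99e-07, adjusted p = 0.314 with an estimated correlation), such as Foxp2 (0.20). GABAergic interneuron genes (median -0.03, mean 0.06, 14 of 30 positive, adjusted p = 0.00509) and neural development genes (median -0.02, mean 0.01, 26 of 62 positive, adjusted p = 0.0123) were called higher against a median of all genes of -0.06, with medians and means of opposite sign. Their adjusted p was 0.153 and 0.499 with an estimated correlation, and the interneuron list did not pass after loess scaling (adjusted p = 0.337). Members were Gad1 (0.59), which makes GABA, Npy (0.38), Eomes (0.67) and Wnt7a (-0.35). When single libraries were left out, relative to the median of all genes, the myelin median went from 0.294 to 0.100 without untreated knockout replicate 2. Hox genes went from 0.498 to 0.853 without untreated knockout replicate 2. Markers of neighbouring regions went from 0.194 to 0.0687 without untreated knockout replicate 1. Interneuron genes went from 0.0230 to 0.161 without untreated knockout replicate 2, 0.0501 without treated knockout replicate 1, 0.121 without treated knockout replicate 2 and 0.00239 without treated knockout replicate 3, and did not pass at -0.00527 without untreated knockout replicate 1. Development genes was 0.0388 with all libraries and did not pass at 0.00631 without untreated knockout replicate 1.

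Astrocyte genes were lower in 25 of 33 members (median log2 -0.17, adjusted p = 0.0145, adjusted p = 0.499 with an estimated correlation), with Gjb6 at 213 ± 17.8 untreated and 148 ± 8.27 treated, a log2 difference of -0.52 and Apoe at -0.32. Oxidative phosphorylation genes were lower in 75 of 77 (median -0.09, adjusted p = 3.61e-05), such as Ndufa4 (-0.18), and ribosomal protein genes in 69 of 74 (median -0.10, adjusted p = 4.28e-05), such as Rps14 (-0.17), both with an adjusted p of 0.652 with an estimated correlation. Unfolded protein response genes were lower in 37 of 41 (median -0.09, adjusted p = 0.0461, adjusted p = 0.831 with an estimated correlation, and 0.146 as adjusted p after loess scaling), such as Hspa5 (-0.21) and Calr (-0.20). Adjusted over the list alone, 6 astrocyte genes were lower and 3 Hox genes higher, and 4 neural development genes were higher and 2 lower, against 0 over all regions tested. Of all genes 73.7% were below 0 here and 53.1% with TMM scaling, where 63 of 77 oxidative phosphorylation, 58 of 74 ribosomal and 29 of 41 unfolded protein response genes were below 0. The median of all genes was -0.06. With 1 library left out and relative to the median of all genes, the astrocyte median was -0.112 with all libraries and did not pass at -0.0612 without untreated knockout replicate 2 and -0.0536 without treated knockout replicate 1. Oxidative phosphorylation genes went from -0.0311 to -0.0481 without untreated knockout replicate 2 and -0.0159 without treated knockout replicate 1. Ribosomal genes was -0.0398 with all libraries and did not pass at -0.0211 without untreated knockout replicate 1. Unfolded protein response genes was -0.0387 with all libraries and did not pass at -0.0208 without untreated knockout replicate 1, -0.0320 without treated knockout replicate 2 and -0.0222 without treated knockout replicate 3.

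By limma 0 regions passed (1755 at an unadjusted p under 0.05, smallest adjusted p = 0.0761), by edgeR 0 (1526) and by DESeq2 29. The count was 205 when wild-type vehicle replicate 3, which adds only to the estimate of spread here, was left out, 363 in a fit of these groups alone, and 3 and 1 without untreated knockout replicate 1 and 2. The myelin medians of single libraries, relative to the vehicle mean, were -0.03 and -0.42 in the untreated knockouts and -0.05 to -0.01 in the treated ones.

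Wild-type mice given SRT2104 were compared with wild-type vehicle mice to ask what the compound does where methionine synthase is present. Thsd4, which encodes a secreted protein with thrombospondin repeats (chromosome 9, 59987283 to 59989300), rose from 108 ± 12.3 to 189 ± 9.999, a log2 difference of 0.81 (SE 0.13, limma adjusted p = 0.0408). No other region passed. Next among higher regions were the serine protease gene Klk8 (274 ± 36.3 and 364 ± 9.74, log2 0.42), Mid1 (0.77), Pyroxd2 (0.49) and the BMP receptor gene Bmpr1b (0.69). Among lower regions they were Rnls (387 ± 38.9 and 285 ± 24.8, log2 -0.44), Trim5 (-1.04), Akna (-0.52), 1810010H24Rik (-0.29) and Ing1, whose product binds H3K4me3 (-0.33).

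Astrocyte genes were higher in 24 of 33 members in treated wild types (median log2 0.06, camera adjusted p = 1.31e-08, adjusted p = 0.110 with an estimated correlation), among them S100b (94.7 ± 15.1 and 130.1 ± 4.93) and Ntsr2 (0.21). The median of all genes was -0.06, and against it 5 further lists were called higher with medians near 0. Excitatory synapse genes had 0.02 (adjusted p = 2.63e-06), with Cacng8 at 0.25, Dlgap1 at 0.20 and Homer1 at -0.16. Hippocampal excitatory neuron genes had a median of -0.02 and a mean of 0.06 (adjusted p = 0.000956), with Zbtb20, a regulator of hippocampal identity, at 356 ± 47.9 and 470.1 ± 52.6. Neural development genes were positive in 30 of 62 (mean 0.01, adjusted p = 0.00213), with Tbr1 at 0.24 and Mki67 at -0.18. Hox genes had 0.09 (adjusted p = 0.0144), with Hoxc13 at 0.68 and Hoxd9 at -0.37, and vascular genes 0.01 (adjusted p = 0.0179), with Slco1c1 at 0.22 and Tbx18 at -0.31. With an estimated correlation the adjusted p was 0.122 for the hippocampal list, 0.432 for the synapse, development and Hox lists and 0.476 for the vascular list. With sex as a covariate the vascular list did not pass by camera (adjusted p = 0.0653), while the Hox list did (adjusted p = 0.0291). Relative to the median of all genes, the Hox and vascular medians were 0.15 and 0.07, and -0.05 and -0.01 after loess scaling, which turned their direction. Unfolded protein response genes were lower in 40 of 41 (median -0.08, adjusted p = 0.0179, adjusted p = 0.903 with an estimated correlation, and 0.301 as adjusted p after loess scaling), such as Hsp90ab1 (-0.15), Atf4 (-0.14) and Ern1 (-0.19). By limma 0 members of these 7 lists passed when adjusted over the list alone. Of all genes 74.4% were below 0 here and 51.9% with TMM scaling, where 28 of 41 unfolded protein response genes were below 0. Relative to the median of all genes, and with 1 library left out, the excitatory synapse median went from 0.0742 to 0.0396 without wild-type SRT2104 replicate 1 and 0.147 without wild-type SRT2104 replicate 2. Hippocampal genes went from 0.0404 to 0.00204 without wild-type SRT2104 replicate 1, 0.103 without wild-type SRT2104 replicate 2 and 0.0806 without vehicle replicate 4. Development genes went from 0.0514 to 0.0339 without wild-type SRT2104 replicate 1, and did not pass at 0.0417 without vehicle replicate 3. Hox genes went from 0.149 to 0.0912 without wild-type SRT2104 replicate 1 and 0.0816 without vehicle replicate 4, and did not pass at 0.0774 without wild-type SRT2104 replicate 2 and 0.0398 without vehicle replicate 3. Vascular genes went from 0.0656 to 0.0225 without wild-type SRT2104 replicate 1 and 0.0989 without wild-type SRT2104 replicate 3, and did not pass at -0.0108 without wild-type SRT2104 replicate 2, 0.0158 without vehicle replicate 2 and 0.0702 without vehicle replicate 3. Unfolded protein response genes went from -0.0198 to -0.0123 without wild-type SRT2104 replicate 1, and did not pass at -0.0150 without vehicle replicate 3.

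Counts at an unadjusted p under 0.05 were 1876 by limma and 1002 by edgeR, which called 0 regions, while DESeq2 called Thsd4 alone. The limma count is 13.4% of regions. It goes with a median log2 difference over regions of -0.0522 on the deposited scaling, which was 0.000271 with TMM. Thsd4 did not pass without wild-type vehicle replicate 2, 3 or 4 or without any of the 3 SRT2104 libraries, or after loess scaling, with an adjusted p of 0.000170 to 0.542 and a log2 difference of 0.74 to 0.87 over all settings. The lists called numbered 4 without vehicle replicate 3, where Hox, development, unfolded protein and vascular genes did not pass, and 10 without SRT2104 replicate 1.

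Treated knockouts were compared with treated wild types to ask what the genotype does under SRT2104. Thy1 rose from 707 ± 61.4 to 1225 ± 123, a log2 difference of 0.79 (SE 0.10, limma adjusted p = 0.0257). No other region passed. Next among higher regions were one shared by Gm12992 and Tmem200b (log2 0.40), Lemd1 (0.25), the glycosylation gene Alg8 (258 ± 18.2 and 315 ± 14.2, log2 0.29) and the metalloprotease gene Mmp24 (0.25). Among lower regions they were Klk8 (364 ± 9.74 and 286 ± 19.1, log2 -0.35), Cntnap5c (-0.40), Thsd4 (-0.50), Drp2 (-0.29) and Folh1 (-0.36).

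Astrocyte genes were lower in 24 of 33 members (median log2 -0.06, camera adjusted p = 1.44e-06, adjusted p = 0.233 with an estimated correlation), with Apoe at -0.20 and S100b at 130.1 ± 4.93 and 105 ± 16.4, a log2 difference of -0.32. Vascular genes were called lower with a mean of -0.05 and 17 of 35 negative, against a median of all genes of 0.04 (adjusted p = 0.00384, adjusted p = 0.957 with an estimated correlation, and 0.719 as adjusted p after loess scaling). The endothelial receptor gene Tek had -0.40 and the transporter gene Slco1c1 -0.29. By limma 0 members of either list passed when adjusted over the list alone. When single libraries were left out, relative to the median of all genes, the astrocyte median went from -0.0934 to -0.0618 without wild-type SRT2104 replicate 1 and -0.0467 without treated knockout replicate 1. Vascular genes went from -0.0347 to -0.0534 without wild-type SRT2104 replicate 1, -0.0923 without wild-type SRT2104 replicate 3 and -0.102 without treated knockout replicate 1, and did not pass at -0.0335 without wild-type SRT2104 replicate 2 and -0.0305 without treated knockout replicate 2. Counts at an unadjusted p under 0.05 were 869, DESeq2 called Thy1 alone and edgeR called 0 regions (536 at an unadjusted p under 0.05). Thy1 did not pass in 6 of the 7 fits that left out a library, each but the one without treated knockout replicate 4, with a log2 difference of 0.71 to 0.87 over all settings.

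Treated knockouts were also set against wild-type vehicle mice, to ask what differs from the control after treatment. Thy1 rose from 649 ± 79.99 to 1225 ± 123, a log2 difference of 0.92 (SE 0.09, limma adjusted p = 0.00180), and it was the region called by limma, by edgeR and by DESeq2, each with 1. Among the higher regions with the next smallest p-values were Mmp24 (483 ± 35.5 and 561 ± 38.96, log2 0.22), Amigo1 (0.20) and Ube2ql1 (0.18). Among lower regions they were Lipo1 (89.97 ± 14.6 and 52.04 ± 7.74, log2 -0.78), Rnls (-0.32), Plxdc1 (-0.17), Gpr19 (-0.17) and Zfp184 (-0.16), and none of these passed.

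Excitatory synapse genes were higher in 42 of 59 members (median log2 0.05, camera adjusted p = 1.50e-07), neural development genes in 42 of 62 (0.01, adjusted p = 0.000218) and hippocampal excitatory neuron genes in 19 of 27 (0.05, adjusted p = 0.000852), with adjusted p of 0.508, 0.508 and 0.258 with an estimated correlation. Cacng8 had 0.15, the axon guidance gene Robo1 0.12 and Fibcd1 0.16. Ribosomal protein genes were lower in 63 of 74 (median -0.04, adjusted p = 0.000719), oxidative phosphorylation genes in 64 of 77 (-0.03, adjusted p = 0.0140) and unfolded protein response genes in 36 of 41 (-0.05, adjusted p = 0.0140), each with an adjusted p of 0.752 with an estimated correlation. Rpl34 had -0.13, Cox7b -0.21 and Dnajb9 -0.10. The median of all genes was -0.02, and 63.7% of them were below 0 here and 51.3% with TMM scaling, where 53 of 74 ribosomal, 52 of 77 oxidative phosphorylation and 34 of 41 unfolded protein response genes were below 0. With 1 library left out and relative to the median of all genes, the excitatory synapse median went from 0.0657 to 0.0340 without vehicle replicate 1, 0.100 without vehicle replicate 3 and 0.0431 without treated knockout replicate 2. Development genes went from 0.0326 to 0.0504 without vehicle replicate 4, and did not pass at 0.0185 without vehicle replicate 3. Hippocampal genes went from 0.0719 to 0.0475 without vehicle replicate 2, 0.0374 without treated knockout replicate 2, 0.0422 without treated knockout replicate 3 and 0.112 without treated knockout replicate 4. Oxidative phosphorylation genes went from -0.0121 to -0.0189 without vehicle replicate 1, -0.0220 without treated knockout replicate 2 and -0.0188 without treated knockout replicate 3, and did not pass at -0.00144 without vehicle replicate 3 and 0.00144 without treated knockout replicate 1. Ribosomal genes went from -0.0194 to -0.0118 without treated knockout replicate 1 and -0.0313 without treated knockout replicate 2, and did not pass at -0.0131 without vehicle replicate 3. Unfolded protein response genes was -0.0277 with all libraries and did not pass at -0.0140 without vehicle replicate 3 and -0.0245 without treated knockout replicate 3. Over the list alone 0 members of these 6 lists passed by limma. At an unadjusted p under 0.05 limma had 303 regions, or 2.16%, below the share that no effect would give on average. With sex as a covariate the hippocampal, oxidative phosphorylation and unfolded protein lists did not pass (adjusted p = 0.130, 0.0944 and 0.0944), and Thy1 did not pass in a fit of the 4 and 4 libraries alone (adjusted p = 0.0658) or in males alone, within a range of 1.48e-15 to 1.00 over all settings. Without wild-type vehicle replicate 3, 3 lists passed, and development, oxidative phosphorylation, ribosomal and unfolded protein genes did not, while 11 passed without vehicle replicate 2.

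The interaction asked whether the difference between treated and control mice depended on genotype. It was more positive in knockouts at 9030624G23Rik (log2 1.00), Wnt10a (1.01), a region of 2210011C24Rik (0.52), the DNA repair gene Fancf (0.49) and Ctsz (0.57). Regions where it was more negative included Thsd4 (-1.02), the tubulin gene Tubb2a (-0.40), a region of Palmd (-0.40) and Pdgfrb (-0.65). None of these passed. The untreated knockouts are labelled as not treated, so the term also holds any effect of gavage.

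By group, the term was positive for myelin genes in 28 of 32 members (median log2 0.33, camera adjusted p = 1.95e-07), Hox genes in 11 of 13 (0.42, adjusted p = 0.00125), choroid plexus and ependyma genes in 11 of 14 (0.34, adjusted p = 0.00125) and markers of neighbouring regions in 29 of 35 (0.16, adjusted p = 0.00783). Zfp488 had 0.73, Hoxd3 1.07, Foxj1 0.47 and Fezf2 -0.67. It was negative for astrocyte genes in 28 of 33 (-0.19, adjusted p = 1.09e-09), excitatory synapse genes in 42 of 59 (-0.09, adjusted p = 1.35e-06), vascular genes in 25 of 35 (-0.08, adjusted p = 0.00888), oxidative phosphorylation genes in 60 of 77 (-0.05, adjusted p = 0.00147) and ribosomal protein genes in 55 of 74 (-0.03, adjusted p = 0.00475). S100b had -0.80, Cacng8 -0.41, Pdgfrb -0.65, Ndufs4 -0.22 and Rpl38 -0.19. With an estimated correlation the adjusted p was 0.0776 for astrocytes, 0.785 for neighbouring regions, 0.867 for oxidative phosphorylation, 0.888 for ribosomal proteins and 0.757 for the other 5 lists. Adjusted over the list alone, 5 astrocyte genes were lower, against 0 over all regions tested. Relative to the median of all genes, and with 1 library left out, the myelin median went from 0.328 to 0.159 without untreated knockout replicate 2. Hox genes went from 0.412 to 0.624 without untreated knockout replicate 2, and did not pass at 0.262 without untreated knockout replicate 1. Choroid plexus genes went from 0.337 to 0.209 without wild-type SRT2104 replicate 1, and did not pass at 0.363 without untreated knockout replicate 1. Markers of neighbouring regions went from 0.149 to 0.0731 without wild-type SRT2104 replicate 1, 0.0876 without vehicle replicate 2 and 0.227 without untreated knockout replicate 2, and did not pass at 0.0602 without untreated knockout replicate 1. Vascular genes went from -0.0876 to -0.137 without wild-type SRT2104 replicate 1, -0.257 without untreated knockout replicate 1 and -0.133 without treated knockout replicate 1, and did not pass at -0.0884 without vehicle replicate 3 and 0.0122 without untreated knockout replicate 2. Oxidative phosphorylation genes was -0.0519 with all libraries and did not pass at -0.0432 without untreated knockout replicate 1. Ribosomal genes went from -0.0393 to -0.0788 without untreated knockout replicate 2 and -0.0237 without treated knockout replicate 1, and did not pass at -0.0172 without untreated knockout replicate 1.

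By limma 0 regions passed for the interaction (1103 at an unadjusted p under 0.05, smallest adjusted p = 0.132), by edgeR 0 (1170) and by DESeq2 13. The count was 272 without wild-type vehicle replicate 3 and 1 or 2 without vehicle replicate 1, either untreated knockout or treated knockout replicate 3, and the vascular list did not pass with sex as a covariate (adjusted p = 0.199). The vascular list also did not pass with a replicate block (adjusted p = 0.0870), and its adjusted p ranged from 7.10e-07 to 0.757 over all settings. Without untreated knockout replicate 1, 4 lists passed, and Hox, choroid plexus, neighbouring-region, oxidative phosphorylation and ribosomal genes did not.

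Whether treatment moved the genotype differences back was examined across the 14006 regions, which are not independent replicates. The untreated knockout minus vehicle difference and the treated minus untreated knockout difference had a Pearson r of -0.868 and a Spearman rho of -0.791. Both hold the untreated knockouts, with opposite sign, so a negative value arises with no effect. Simulated unchanged groups, with noise drawn independently for each region, gave an r of -0.658 ± 0.0414 (SD of 100 draws). Relabelling the libraries gave an r of -0.876 to -0.186, and 3 of 100 relabellings gave one as low. The covariance was -0.0421, against -0.0134 ± 0.00195 in the simulation and a lowest value of -0.0396 in the relabellings. Anything else that the untreated knockouts share, such as sex or the lack of gavage in their labels, would also lower both values. Neither value therefore shows that treatment moved the differences back. Thy1, the 1 region called in untreated knockouts, did not have a smaller difference from vehicle in treated knockouts.

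The share of signal in the highest promoters passed in none of the 3 tests made, and comparisons with untreated knockouts were not tested. The 1000 highest regions took 16.6% ± 0.0856 of reads in wild-type vehicle, 16.3% ± 0.134 in wild-type SRT2104, 16.7% ± 0.453 in untreated knockouts and 16.6% ± 0.381 in treated knockouts. Exact two-sided permutation tests gave p = 0.0857 for wild-type SRT2104 against vehicle, p = 0.457 for treated knockouts against treated wild types and p = 0.971 for treated knockouts against vehicle, where the smallest possible p was 0.0286.

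Pathways that the knockout and the compound target passed as groups in none of the comparisons. In untreated knockouts against vehicle, methionine and folate cycle genes had a median log2 of 0.01 over 41 genes (camera adjusted p = 0.158), cobalamin genes 0.01 over 21 (0.267) and H3K4 methylation and demethylation genes 0.05 over 32 (0.110). Sirtuin and NAD genes had 0.03 over 20 (0.610) and SIRT1 substrates 0.03 over 37 (0.790), beside a median of all genes of 0.03. In treated against untreated knockouts the medians in the same order were -0.05, -0.05, -0.07, -0.05 and -0.06, beside -0.06 for all genes. By limma 0 members of these 5 lists passed in any comparison, over all regions tested or adjusted over the list alone.

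Some class I histocompatibility genes on chromosome 17 had values that followed single libraries, and were chosen after their values were seen. Of the 20 regions of H2 genes measured on that chromosome, only some are described. H2-K1 (34136260 to 34137583), which presents peptides to T cells, had 60.9 in untreated knockout replicate 2 and 292 in replicate 1. It had 475, 483, 547 and 489.8 in wild-type SRT2104 replicate 3, vehicle replicates 2 and 4 and treated knockout replicate 4, and 276 to 319 in the other 7 libraries. H2-T23 (36168565 to 36169861) had 71.6 in untreated knockout replicate 2, 401 to 417 in the same 4 libraries and 220.1 to 279 in the rest, while H2-D1 had 562 to 704 over all 13. The order was opposite at H2-T3, with 40.3 in untreated knockout replicate 2, 3.52 to 5.11 in those 4 libraries and 13.5 to 29.7 in the rest. H2-Q1 had 111, 52.5 to 59.7 and 51.02 to 84.8 in the same order of libraries, the lowest being untreated knockout replicate 1.

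**Figure D4:**
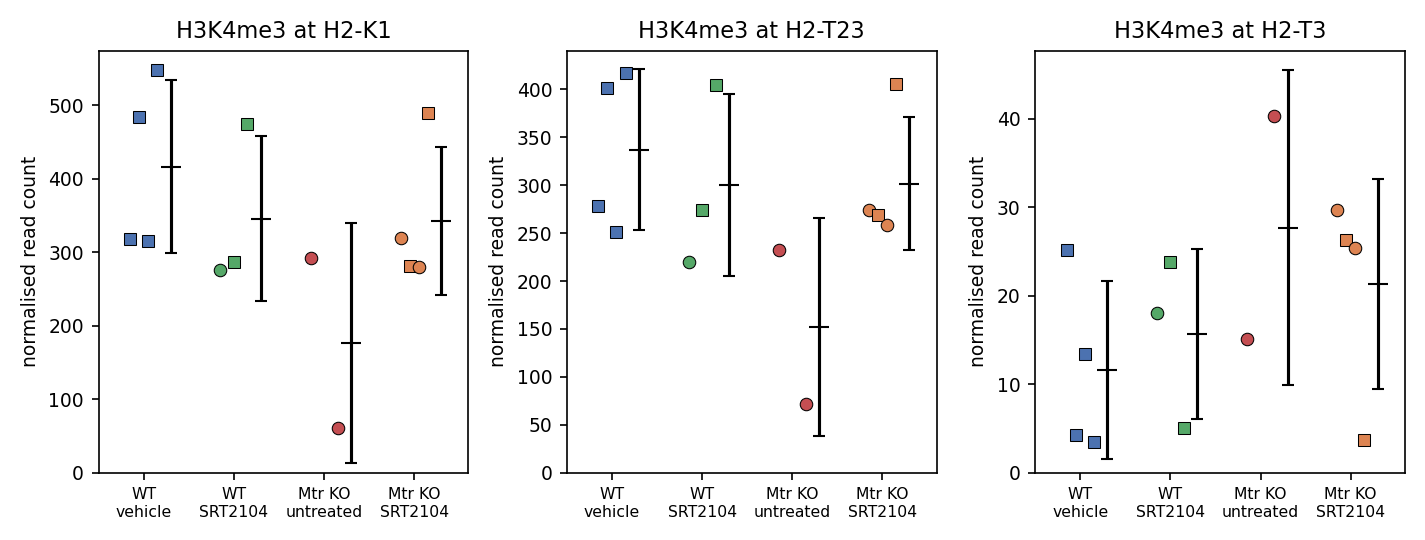
Normalised read count per library at histocompatibility regions of chromosome 17, with colour for group. At H2-K1 untreated knockout replicate 2 lies at 60.9 and the other 12 libraries between 276 and 547.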

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

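The tests of the 3 patterns weighed here were all chosen only after the result was seen, while the counts over other splits of the libraries were planned. In the wild-type vehicle group replicate 3 lay far from the other 3 libraries for myelin genes (-0.365 against 0.0591 to 0.138, as the median log2 difference from the group mean). The same held for oxidative phosphorylation (0.0684 against -0.0256 to -0.0177) and cholesterol synthesis genes (0.0430 against -0.0190 to -0.0164). These are 3 of 60 groups of values tested, where chance gives about 3 if they are independent. The groups share libraries and all 3 flags fell on vehicle replicate 3, so the count does not judge that library. The interaction term passed for 9 lists with a preset correlation, and for 0 of them with an estimated correlation (adjusted p = 0.0776 to 0.888). The medians were 0.335 for myelin, 0.419 for Hox, 0.344 for choroid plexus and 0.156 for neighbouring-region genes. They were -0.185 for astrocyte, -0.0881 for excitatory synapse, -0.0809 for vascular, -0.0452 for oxidative phosphorylation and -0.0326 for ribosomal protein genes.

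Thy1 signal was higher in all 6 knockout libraries than in all 7 wild-type libraries, with a gap of 265 between the lowest knockout and the highest wild type. Sex alone is argued against, since among males the difference was 0.836 (2 knockouts against 6 wild types). A wider copy change is argued against as well, since the other 21 regions within 500 kb had a median difference of 0.00562 (range -0.620 to 0.0996). Reads from the Thy1 promoter of the Cre transgene cannot be told apart from more H3K4me3 at the gene itself through loss of Mtr. The gap restates the pattern and both would give it, the knockouts carry the transgene by design, and the labels do not say whether wild types do.

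The untreated knockouts lay apart from the treated ones on the first component, and wild-type vehicle replicate 3 lay with them. Its difference from the wild-type SRT2104 libraries correlated with the untreated knockout minus other vehicle difference at r = 0.311, but it was picked for that position and 247 of 1000 relabellings of the libraries had a highest r as large, so an axis of tissue content cannot be told apart from other structure. The tables argue against sex alone, since the highest first-component score of the other 3 females was -3.95 and vehicle replicate 3 is male. These 3 females were all given SRT2104, and the component leaves out chromosomes X and Y, so an effect of sex without SRT2104 stays open. The tables also argue against genotype alone, since the highest score of the treated knockouts was -0.720. Both scores stay below 0 without chromosome 17 (-4.67 and -2.95), which holds 18.2% of the squared loadings. At the preset correlation 6 of the 8 lists passed in the same direction after scaling by region height. With an estimated correlation 0 lists passed before that scaling. In the comparisons with at least 3 libraries per group, other splits of the libraries also gave 6 or more lists. The lists that stayed therefore do not decide on immunoprecipitation efficiency. It stays open, as do tissue taken with the hippocampus, gavage, SRT2104 acting on the knockout, and a batch that the labels do not give.

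Signal at some histocompatibility genes of chromosome 17 was graded between libraries. The 100 most variable autosomal regions, among which these genes were found, put 7 in 1 window of 5 Mb with any start (up to 6 in 1000 random draws) and 5 in 1 of the fixed windows used first (up to 6). The count restates how the genes were found and depends on the window. Segregating haplotypes therefore cannot be told apart from other causes by it. All 6 linked regions compared had the library order of H2-K1, with untreated knockout replicate 2 lowest and the same libraries highest. These regions were drawn from the same 100, so their order does not decide either. At H2-T3 the order was opposite. Neither a library-wide change (median -0.00648 over the 643 other regions of the chromosome in untreated knockout replicate 2) nor microglia content (median 0.0314 over 16 genes) showed the change expected of it. Haplotypes stay open, and no explanation from the groups of the design was tested.

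In the comparisons with at least 3 libraries per group, chance could not be excluded for the counts of regions or lists. Of 35 splits, 3 gave at least the 1 region of wild-type SRT2104 against vehicle, and the highest other split gave 19. For treated knockouts 6 splits gave at least the 1 region against treated wild types (highest other 13), and 9 gave at least the 1 against vehicle (highest other 4). Among those 6, a split with 12 regions set all males against all females, so its calls can reflect sex. A count also leaves out how far a call lies past the threshold, so the splits do not judge a single call such as Thy1. For gene lists 12 splits gave at least the 7 lists of wild-type SRT2104 against vehicle (highest other 11). In the same way 24 gave at least the 2 of treated knockouts against treated wild types (highest other 7), and 23 at least the 6 against vehicle (highest other 10).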

How the results depend on the processing

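The test named in the design, edgeR with TMM, was run on the recovered reads as an alternative to limma. It called 1 region for treated knockouts against vehicle and 0 in the other comparisons and the interaction. Tests on loess-scaled values, on males alone, with a pseudocount of 8, and those combining the loss of wild-type vehicle replicate 3 with another change were chosen only after the result was seen. So were the fit lacking that library where it is in neither group, the sex covariate for gene lists and the reversal without that library. Over all pairs of a main result and an alternative other than leaving out a library, 100 kept the value, within 1.5 times for counts, and 62 moved. Over such pairs for called gene lists, 163 kept direction and call, 57 kept direction only and 2 turned. Over those for named regions, 4100 kept direction and side of the threshold, 213 newly passed, 29 no longer passed and 39 turned. The lost calls were Thy1 and Thsd4. No named region turned in a comparison where it was called, and the changes of sign are given here as log2 differences. Sirt1 in untreated knockouts, treated against untreated knockouts and treated knockouts against vehicle (0.0157, -0.0207 and -0.00504 by limma) had -0.0147, 0.0245 and 0.00979 with DESeq2 size factors in edgeR, -0.0228, 0.0293 and 0.00642 with library size only in edgeR, -0.0292, 0.0414 and 0.0121 with a loess offset in edgeR. It had -0.0146, 0.0265 and 0.0119 by the DESeq2 Wald test, -0.0164, 0.0251 and 0.00870 by edgeR with TMM, -0.0295, 0.0443 and 0.0148 on loess-scaled values. For the first 2 of these it had -0.0284 and 0.0263 with voom weights, and without vehicle replicate 3 -0.0481 and 0.0443 with loess scaling and -0.0318 and 0.0240 by edgeR. For the last 2 it had 0.00426 and 0.0548 on loess-scaled values with sex, and for the last 0.0409 with the sex covariate and 0.0371 with it and without vehicle replicate 3. Mtr in the interaction (-0.00566) had 0.00246 with library size only, 0.0324 with voom weights and 0.00138 by edgeR with TMM, and without vehicle replicate 3 0.00374 with loess scaling and 0.0137 by edgeR. Mtr in treated against untreated knockouts (0.00352) had -0.00346 with the sex covariate and -0.00346 with it and without vehicle replicate 3, and in wild-type SRT2104 (0.00918) -0.00935 among males. Thy1 in the interaction (-0.0634) had 0.0692 with the sex covariate and 0.0733 with loess scaling as well, which also took Hoxc9 in wild-type SRT2104 from 0.289 to -0.0843. Untreated knockout against vehicle, wild-type SRT2104 against vehicle and treated knockout against treated wild type, each with 1 region, had 0, 0 and 0 with DESeq2 size factors in edgeR. They had 0, 0 and 0 with library size only in edgeR, 0, 0 and 0 with a loess offset in edgeR, and 0, 0 and 0 by edgeR with TMM (1357, 1002 and 536 at an unadjusted p under 0.05). On loess-scaled values limma gave 0, 0 and 0, and with sex as a covariate as well 0, 0 and 0. The sex covariate alone gave 0 for untreated knockouts by limma (831 at an unadjusted p under 0.05). The DESeq2 Wald test gave 25 there, 29 for treated against untreated knockouts and 13 for the interaction, against 1, 0 and 0. With voom weights the counts were 0 for untreated knockouts and 2 for treated knockouts against vehicle. In fits of only the groups compared they were 47 for untreated knockouts against vehicle, 363 for treated against untreated knockouts, 3 for wild-type SRT2104 and 0 for treated knockouts against vehicle. Libraries with the same replicate number were no more alike than others (median r -0.0905 for 16 pairs and 0.0370 for 46 others), and with the number as a replicate block the counts were 2 for untreated knockouts and 0 for wild-type SRT2104. Among males alone, with 2 treated knockouts and 2 treated wild types, limma gave 0, 0 and 0 for wild-type SRT2104 against vehicle and treated knockouts against treated wild types and against vehicle (787, 169 and 372 at an unadjusted p under 0.05). The fit lacking wild-type vehicle replicate 3 gave 205 for treated against untreated knockouts. Without that library and with the sex covariate the counts were 136 for untreated knockouts, 200 for treated against untreated knockouts, 0 for wild-type SRT2104 and 139 for the interaction. With loess scaling instead they were 471, 225, 0 and 303, with 0 for treated knockouts against treated wild types and 2 against vehicle. By edgeR they were 579, 263, 0 and 246, with 2 for treated knockouts against vehicle. These counts rest on a library singled out after its values were seen, so p-values are too small where it is in a group compared. For treated against untreated knockouts it adds only to the estimate of spread, and whether p-values are too small there was not tested. The fit of those groups alone, which holds no wild type, called 363. The cause of each move was not tested. The gene lists called, in the order untreated knockouts, treated against untreated knockouts, wild-type SRT2104, treated knockouts against treated wild types, against vehicle, and interaction, were 8, 10, 7, 2, 6 and 9. With an estimated correlation they were 0, 0, 0, 0, 0 and 0, and by fry 1, 2, 0, 0, 0 and 1. With loess-scaled values 4 passed for wild-type SRT2104, where, relative to the median of all genes, the vascular median turned from 0.0656 to -0.0136 and the Hox median from 0.149 to -0.0523.

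Leaving out each library in turn gave 0 to 564 regions for untreated knockouts against vehicle (highest without vehicle replicate 3), 0 to 3 for treated against untreated knockouts, 0 to 2 for wild-type SRT2104, 0 to 1 for treated knockouts against treated wild types, 1 to 1 against vehicle and 0 to 272 for the interaction (highest without vehicle replicate 3). Where 1 untreated knockout was left, it is assumed to vary like the other groups. The lists called ranged over 6 to 13, 10 to 13, 4 to 10, 1 to 3, 3 to 11 and 4 to 9 in the same order, and the reversal r over -0.916 to -0.894 without either untreated knockout, and was -0.892 without vehicle replicate 3. Relative to the median of all genes, the ribosomal median in untreated knockouts was -0.00159 to 0.0379, lowest without untreated knockout replicate 1, and the vascular median of the interaction -0.257 to 0.0122, highest without untreated knockout replicate 2, while the vascular median of wild-type SRT2104 was -0.0108 to 0.0989, lowest without SRT2104 replicate 2. For named regions, leaving out a library kept direction and side in 1807 pairs, while 47 newly passed, 15 no longer passed and 21 turned, none where it was called. The log2 of Mtr was -0.196 to 0.0604 for untreated knockouts against vehicle, -0.125 to 0.132 for treated against untreated knockouts and -0.134 to 0.123 for the interaction, and that of Thy1 -0.0469 to 0.173 and -0.173 to 0.0466 for the last 2. That of Sirt1 was -0.0937 to 0.125 and -0.130 to 0.0887 for the first 2. The ends of these 7 ranges came without untreated knockout replicate 1 or 2. Mtr was -0.0115 to 0.0484 for wild-type SRT2104, without SRT2104 replicate 2 and 3, and Sirt1 -0.0370 to 0.0457 for treated knockouts against vehicle, without treated knockout replicate 1 and 2. Depth was 277 reads for the median region of the shallowest library.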

Other observations

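The tests without wild-type vehicle replicate 3 in this part were chosen only after the result was seen. The other 7 gene lists passed in none of the comparisons by camera. In untreated knockouts against vehicle the median log2 was 0.01 for fatty acid oxidation (adjusted p = 0.377), 0.02 for cholesterol synthesis (0.955), -0.02 for microglia (0.273) and 0.03 for DNA and other methyltransferases (0.790), beside 0.03 for all genes. Immediate early genes, which respond to neuronal activity, had 0.05 (0.273) and imprinted genes 0.06 (0.273). Sex chromosome markers had 0.73 over 8 genes (0.445), where females are compared with males. Adjusted over the list alone, 5 sex markers were higher and 3 lower there, and in treated against untreated knockouts 6 immediate early genes were lower and 1 higher (list adjusted p = 0.225) and 2 imprinted genes lower (0.0726), against 0 over all regions by limma.

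With wild-type vehicle replicate 3 left out, some genes had more signal in untreated knockouts than in the other 3 vehicle libraries. Examples are the transcriptional regulator gene Runx1t1 (633 ± 58.4 in 3 vehicle libraries, 957 and 1140.2 in untreated knockouts, 995 in vehicle replicate 3 and 694 ± 30.5 in treated knockouts) and the muscarinic receptor gene Chrm4 (500.1 ± 24.1, 710.5 and 865, 886 and 559 ± 44.4 in the same order). Lower ones were Pappa (674 ± 30.9, 480.0 and 505, 469 and 629.8 ± 24.7), the fatty acid transport gene Cpt1a (910.1 ± 64.9, 729 and 732, 721 and 848 ± 39.4) and the growth factor receptor gene Erbb3 (606 ± 35.03, 546 and 450.2, 445 and 575 ± 12.6). Leaving out a library because it resembles the other group lowers p-values by construction, so these genes are given as values and not as calls.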
